A study of Mus musculus with 23 samples.

How the data were processed

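RNA of mouse embryonic fibroblasts with H-RasV12 was measured on Affymetrix oligonucleotide arrays, with 1 column of values per sample and 23 samples. The authors deposited RMA values per probe set as an intensity on a linear scale, from 8.548 to 32042.1, and did not state the version or the options of RMA. The values were taken to log2. The median intensity of an array lay between 59.9 and 64.22, and the number of arrays, 3 to 6 per group, limits the precision.

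Of 45101 probe sets, 64 control probe sets were left out and 45037 remained. Of these 34945 carried 1 gene symbol, 932 carried several and 9160 were not listed in the annotation. The last 2 kinds were left out of the gene tables. Each of the 18193 genes was represented by its probe set with the highest mean over all arrays. Genes were tested when at least 3 arrays lay above the 30th percentile of all values (log2 4.79), which left 15266. Genome positions of the probe sets are not used here.

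Groups followed the sample titles. WT joined LSL-WT with Cre virus (replicates 1 to 3) and WT with Cre virus (replicates 4 to 6), and Null joined LSL-WT with Empty virus (replicates 1 to 3) and Null with Cre virus (replicates 4 to 6). The arrays came from a 129 background or a mixed one: 4 and 1 in 25,26, 1 and 2 in 53,54, 2 and 1 in QM, 3 and 3 in WT, and 4 and 2 in Null. For WT replicate 6 the genotype label differed from the title, and the label of Null replicate 6 added the word knock-in. The labels do not say whether the replicates were separate embryos, separate cultures or repeats of 1 culture, so every p-value measures only the spread between these samples. Xist, the transcript of the inactive X chromosome, lay above a log2 level of 8 in 4 of 5 25,26, 1 of 3 53,54 and 2 of 3 QM arrays. This argues against repeats of 1 culture for all arrays of these groups.

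A 5-group means model was fitted with limma 3.58.1 in R 4.3.3 to all 23 arrays, with its default moderated two-sided test and Benjamini-Hochberg adjustment over the genes tested. The threshold was an adjusted p of 0.05. A model of 7 subgroups gave the parts of the WT comparison, LSL-WT Cre with LSL-WT Empty (the LSL-WT part) and WT Cre with Null Cre, and their interaction. Fixed gene lists were tested with camera at a preset correlation of 0.01, adjusted over 24 lists in each comparison, and again with an estimated correlation. The list of erythroid markers had too few measured genes and was not tested, and the sex-linked list was used only to check labels. The 100 genes with the highest and the 100 with the lowest moderated statistic in the LSL-WT part formed the scores, tested with exact two-sided permutation tests. The correlation of effects was computed with shared and with split Null arrays and in 100 simulations of unchanged groups.

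Groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. In each comparison with Null the rule took the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, and the 5 and 5 in the comparisons with WT and of 25,26 with QM. It added up to 4 genes per fixed list with the largest moderated statistic, and every member of the p53 lists. The transcripts of the targeted gene and of H-Ras are not analysed here, and some other list members are not reported here.

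Whether equal title numbers pair arrays across groups was checked from the correlation of the residuals of same-number arrays. The check called 53,54 with Null, 25,26 with WT and the LSL-WT part paired. It asked every same-number pair to pass a set correlation. Comparisons that missed this had the same structure, as WT with Null (9 of 10 pairs passed, median 0.314 against -0.176 for other numbers). In QM with Null 4 of 5 passed (0.522 against -0.252). In the LSL-WT part these correlations were 0.72 to 0.804, with a median of 0.736, against -0.544 for other numbers. Counts with the title number as a block are given beside the others in these and further comparisons. The first principal component within subgroups held 39.7% of the variance.

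The method was tested on simulated data with the spread of these arrays, with 200 changed genes among 15266. It recovered 66% of log2 changes of 0.5 and 94% of changes of 1 at the sizes of WT and Null, 41% and 89% for 25,26, 42% and 80% for 53,54 and 42% and 88% for QM. False calls were 10 of 170, 3 of 133, 6 of 128 and 4 of 134. Each simulated array was drawn independently, without the correlation between arrays of 1 title number. These rates therefore may not hold for the real arrays.

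The alternatives were no filter, a mean above the median (11470 genes), the mean of a gene's probe sets, all probe sets, quantile normalization, median centring, the strain background as a covariate, the title number as a block, trended and robust variances, array weights, the compared arrays alone, each array left out in turn, Null Cre arrays alone, LSL-WT Cre arrays alone as WT, and scores of 50 or 200 genes or with the parts swapped between choosing and scoring. The level of Xist as a covariate, the arrays without title number 2 and the arrays without differing labels were added after seeing the data. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.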

Results

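Gene expression was measured on 23 oligonucleotide arrays, 1 per sample, in mouse embryonic fibroblasts that carried the oncogene H-RasV12 and differed in p53, the tumour-suppressor transcription factor. The fibroblasts held knock-in alleles behind a stop cassette (LSL) that Cre recombinase, delivered by adenovirus, removes. The WT group (n = 6) had wild-type p53 and the Null group (n = 6) had none. The 25,26 group (n = 5) carried changes in the first activation domain of p53, the 53,54 group (n = 3) carried changes in the second, and the QM group (n = 3) carried both sets. The WT group joined 3 LSL-WT arrays and 3 WT arrays with Cre virus, and the Null group joined 3 LSL-WT arrays with Empty virus and 3 Null arrays with Cre virus. The median intensity per array lay between 59.9 and 64.22. Xist, the transcript of the inactive X chromosome, had a log2 level above 8 in 4 of 5 25,26 arrays, 1 of 3 53,54 arrays, 2 of 3 QM arrays, 4 of 6 WT arrays and 1 of 6 Null arrays, so the sex of the embryos was not balanced between groups.

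The comparison of WT with Null asked which genes depended on p53 in fibroblasts with H-RasV12. Members of the p53 target lists and genes on no list were among the largest rises in WT. Psrc1, a p53 target which encodes a spindle-associated protein, was higher by 5.73 ± 0.21 (log2 difference ± SE, n = 6 and 6), and Perp, a desmosome-associated apoptosis gene, by 5.25 ± 0.35. Sulf2, an extracellular sulfatase acting on heparan sulfate and on none of the lists, rose by 5.03 ± 0.20. Cdkn1a, the cyclin-dependent kinase inhibitor of the p53 arrest response, rose by 2.53 ± 0.21 (adjusted p = 1.98e-08), and Mdm2, the ubiquitin ligase that limits p53, by 2.66 ± 0.13 (adjusted p = 2.84e-12). Among the genes that fell were Cdc6, an origin-licensing factor, at -2.18 ± 0.33, Bub1, a spindle-checkpoint kinase, at -2.04 ± 0.28, and the chemokine gene Cxcl10 at -2.92 ± 0.42 (adjusted p = 2.83e-05).

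Of 20 measured p53 targets of cell-cycle arrest and feedback, 14 rose and 1 fell in WT, with 14 and 2 adjusted over the list alone. Ccng1, a cyclin gene, rose by 3.30 ± 0.09, Zmat3, an RNA-binding protein gene, by 2.56 ± 0.13 and the antiproliferative gene Btg2 by 2.23 ± 0.24. The member that fell was Cdkn2d, a cyclin-dependent kinase inhibitor, at -0.88 ± 0.10. Of 18 apoptosis targets 15 rose and 1 fell, over all genes and adjusted over the list alone. Pmaip1, which encodes the cell-death protein Noxa, rose by 3.35 ± 0.38 and the receptor gene Eda2r by 4.01 ± 0.21. The death-receptor gene Fas rose by 1.56 ± 0.21, and Phlda3, an inhibitor of Akt, rose by 3.09 ± 0.16. Of 16 DNA repair and redox targets 10 rose and 2 fell, with 12 and 3 adjusted over the list alone. Ephx1, an epoxide hydrolase, rose by 4.02 ± 0.21, the excision-repair nuclease gene Ercc5 by 2.17 ± 0.10 and the translesion polymerase gene Polk by 2.06 ± 0.18. Pcna, the sliding clamp of replication, fell by 0.73 and the mitochondrial dismutase gene Sod2 fell by 0.48. The 3 lists tested higher in WT with limma camera at adjusted p of 1.43e-15, 8.48e-17 and 1.17e-07, and of 0.00182, 8.57e-04 and 0.00219 with an estimated correlation. Some recognised targets did not pass: Gadd45a had a log2 difference of 0.00 ± 0.13 (adjusted p = 0.998), Sesn1 of -0.21 ± 0.08 (adjusted p = 0.0785, or 0.0239 with the title number as a block) and Ddb2 of -0.18 ± 0.17 (adjusted p = 0.523).

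All 31 measured genes of mitosis and G2/M fell in WT, over all genes and adjusted over the list alone, with a median log2 difference of -1.64 and an adjusted p of 3.17e-24, against an adjusted p of 0.118 with an estimated correlation. The kinetochore gene Cenpf fell by 1.99, the mitotic kinase gene Aurkb by 1.89 and the condensin gene Ncapg by 2.09. Of 29 genes of DNA replication and G1/S 26 fell, over all genes and adjusted over the list alone, at an adjusted p of 1.91e-19 (0.0872 with an estimated correlation). The clamp-loader gene Rfc4 fell by 1.44 and the exonuclease gene Exo1 by 2.05. Over the 60 genes of both lists, each of the 7 arrays with the number 2 in its title had a mean below that of the other arrays of its subgroup.

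Of 20 interferon-response genes 6 fell in WT, over all genes and adjusted over the list alone, at an adjusted p of 4.17e-05 (0.475 with an estimated correlation). Besides Cxcl10, the antiviral genes Oasl1 and Rsad2 were among them, at -1.93 ± 0.38 and -1.07 ± 0.32. Of 15 cholesterol-synthesis genes 10 fell (12 adjusted over the list alone), at an adjusted p of 6.87e-06 (0.271 with an estimated correlation), including the synthase genes Hmgcs1 at -0.76 ± 0.16 and Lss at -0.82 ± 0.17. Of 21 genes of extracellular matrix and fibroblast identity 7 fell (8 adjusted over the list alone), at an adjusted p of 0.0107 (0.537 with an estimated correlation). These included the proteoglycan genes Lum at -1.99 ± 0.50 and Dcn at -1.09 ± 0.25 and the growth-factor receptor gene Pdgfra at -1.23 ± 0.32. Of 31 senescence-associated secreted factors 2 rose and 1 fell (2 and 0 adjusted over the list alone). The adhesion gene Icam1 rose by 2.21 ± 0.32, and the list's median of -0.05 and mean of -0.10 were negative while its test pointed up (adjusted p = 0.999). Of 15 contractile genes 4 rose, over all genes and adjusted over the list alone, at an adjusted p of 0.0233 (0.382 with an estimated correlation). The calls of Lmod1, Tagln and Tpm2 each ended without WT replicate 4, and again without WT replicate 6. Of 14 NF-kB genes 2 rose and 3 fell (2 and 4 adjusted over the list alone; adjusted p = 0.397), with the chemokine gene Ccl5 at -1.80 ± 0.46.

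Markers of other cell types were measured beside these groups. Of 12 epithelial markers 4 rose in WT, over all genes and adjusted over the list alone, at an adjusted p of 0.0345 (0.185 with an estimated correlation), with the desmosome gene Dsp higher by 3.10 ± 0.42 and the keratin gene Krt19 by 1.28 ± 0.36. The tests of the macrophage, endothelial, muscle, neural, adipocyte and cartilage lists gave adjusted p between 0.915 and 0.999. In these lists Cd68, a macrophage lysosomal gene, rose by 1.25 ± 0.31 and the skeletal actin gene Acta1 by 1.79 ± 0.31.

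With limma, 1668 genes were higher and 1797 lower in WT than in Null at an adjusted p under 0.05, of 15266 tested, and 305 and 335 of these differed at least 2-fold. Over all probe sets the total of 3465 became 5746, and with the title number as a block it became 5160. The groups differed in virus and in embryos as well as in p53, and whether arrays of 1 group came from separate embryos was not stated.

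**Figure D1:**
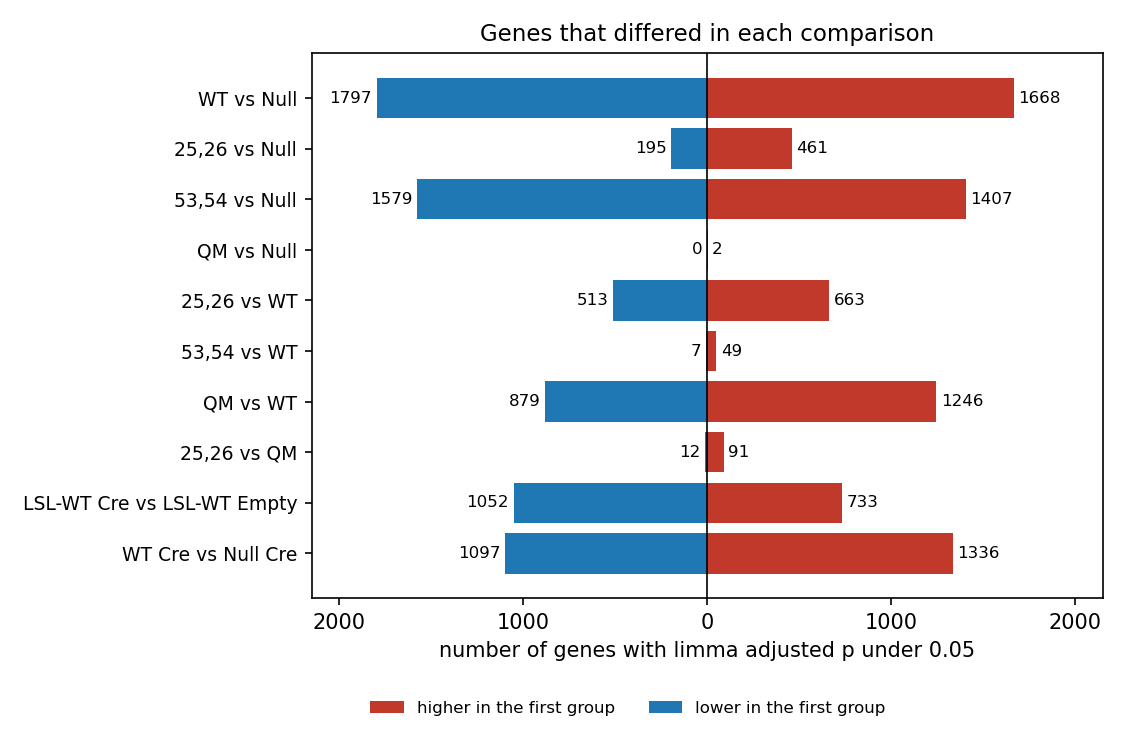
Number of genes with a limma adjusted p under 0.05 in each comparison, drawn as bars to the right for genes higher in the first group and to the left for genes lower in it. WT had 1668 genes higher and 1797 lower than Null, and QM had 2 higher and 0 lower.

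The WT comparison was repeated in separate parts, which shared no array. In the first, LSL-WT cells with Cre virus were compared with LSL-WT cells with Empty virus (n = 3 and 3), which asked for the effect of switching on 1 allele. Psrc1 rose by 5.46 ± 0.27, Perp by 4.53 ± 0.43, Sulf2 by 4.76 ± 0.27, Mdm2 by 2.94 ± 0.15 and Cdkn1a by 2.92 ± 0.27, while Cdc6 fell by 2.33 and Ncapg by 2.29. In the second, WT cells with Cre were compared with Null cells with Cre (n = 3 and 3), which asked the same of separate lines with the same virus. The log2 level of Xist was 11.47 to 11.86 in these WT arrays and 5.72 to 6.81 in these Null arrays, so sex was fully confounded with p53 in the second part. Psrc1 rose by 5.99 ± 0.27, Perp by 5.97 ± 0.43, Sulf2 by 5.29 ± 0.27, Mdm2 by 2.39 ± 0.15 and Cdkn1a by 2.14 ± 0.27. The largest falls in the second part included Cxcl10 at -3.79 ± 0.56 and the acute-phase gene Saa3 at -3.50 ± 0.78. In the first part Cxcl10 was at -2.05 ± 0.56 (adjusted p = 0.0194, or 0.00344 with the title number as a block), a call that ended without WT replicate 1 or 2 or Null replicate 3, at -2.04, -1.46 and -1.42 and adjusted p of 0.0518, 0.146 and 0.131. Oasl1 fell by 2.71 in the second part, and had a log2 difference of -1.15 ± 0.48 (adjusted p = 0.141) in the first.

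The first part had 733 genes higher and 1052 lower, and its total of 1785 became 4078 when the title number, which paired these arrays, entered as a block (4667 within these 6 arrays alone), 807 with the compared arrays alone, 1157 without the arrays of title number 2 and 2813 over all probe sets. Without WT replicate 2 it was 994. The second part had 1336 genes higher and 1097 lower, and its total of 2433 became 4297 with the block, 1186 with the compared arrays alone, 1306 with the level of Xist as a covariate and 4236 over all probe sets. The test of the difference between the parts passed for 1 gene of 15266 in limma (1193 at an unadjusted p under 0.05), and for 245 genes, 67 higher and 178 lower, with the title number as a block. That gene, Lrp11, was chosen after its values were seen: its log2 difference was 0.17 ± 0.18 in the first part and 1.89 ± 0.18 in the second (adjusted p of the difference = 0.0363). The count of 1 became 0 without WT replicate 1, 2 or 3 or Null replicate 1, 2, 3, 5 or 6, 3 without WT replicate 5 and 47 without WT replicate 6. It was 0 with the compared arrays alone or with the level of Xist as a covariate, and 2 to 24 under 8 other settings, with 24 from array weights.

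The comparison of 25,26 with Null asked what p53 with a disrupted first activation domain still did. Sulf2 rose by 4.63 ± 0.21 (n = 5 and 6, adjusted p = 3.36e-12), Perp by 3.06 ± 0.37 and Crip2, a LIM-domain protein gene, by 2.88 ± 0.20. Def6 rose by 2.65 ± 0.18, and Ccng1 by 2.33 ± 0.10. Mdm2 rose by 1.17 ± 0.14 (adjusted p = 1.22e-05). Cdkn1a rose by 0.78 ± 0.22 at an adjusted p of 0.0471, and this call ended when any of 10 of the 11 arrays was left out, those being 25,26 replicates 1 to 5 and Null replicates 1, 2, 3, 5 and 6. Without each of these in turn the log2 difference of Cdkn1a lay between 0.62 and 0.84, with adjusted p from 0.0546 to 0.15, and with no filter on low values the adjusted p was 0.0533. With the title number as a block Cdkn1a was higher by 0.91 (adjusted p = 4.18e-04).

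Of 20 targets of arrest and feedback 8 rose and 1 fell (11 and 1 adjusted over the list alone). Besides Cdkn1a, the calls of Plk2 and Ptprv ended for 7 and 10 of the 11 arrays left out in turn. All 3 ended without 25,26 replicate 1. Psrc1 rose by 2.10 ± 0.21, Trp53inp1, a stress and autophagy gene, by 2.65 ± 0.21 and Zmat3 by 1.93 ± 0.13, and Cdkn2d fell by 0.53. Btg2 at 0.60 ± 0.25 (adjusted p = 0.214) and Rprm, a gene of G2 arrest, at 0.31 ± 0.21 (adjusted p = 0.519) did not pass. Of 18 apoptosis targets 9 rose (11 rose and 1 fell adjusted over the list alone). Pmaip1 rose by 1.48 (limma adjusted p = 0.0362), a call that ended for 6 of the 11 arrays left out in turn. With the title number as a block Pmaip1 was higher by 1.80 (adjusted p = 1.92e-04). The apoptosome gene Apaf1 rose by 1.38 ± 0.14, Eda2r by 1.65 ± 0.22 and Phlda3 by 1.26 ± 0.17. Fas at 0.55 ± 0.22 (adjusted p = 0.194) and Bbc3, which encodes the cell-death protein Puma, at 0.15 ± 0.18 (adjusted p = 0.767) did not pass. Of 16 repair and redox targets 5 rose and 1 fell (8 and 2 adjusted over the list alone), among them Polk at 1.75 ± 0.19, Ercc5 at 1.49 ± 0.11 and the alkylation-repair gene Mgmt at 1.48 ± 0.15. With an estimated correlation the 3 lists had adjusted p of 0.00402, 0.0037 and 0.00308. Of 11 genes recalled from published work as retained by 25,26, 10 rose (11 adjusted over the list alone), including Abhd4, a lipid hydrolase gene, at 1.26 ± 0.10 and Sidt2, a lysosomal membrane gene, at 1.29 ± 0.11. That list was in part chosen on these samples, so its count is not independent evidence.

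No gene of the mitosis list (0 of 31) or the replication list (0 of 29) passed in 25,26 against Null with limma, nor adjusted over the list alone, where 2521 genes in all had an unadjusted p under 0.05. Off these lists, the mitotic regulator gene Fbxo5 passed as lower. That call ended for 4 of the 11 arrays left out in turn. With the title number as a block 14 genes of each list were lower, Cdc6 among them (adjusted p = 0.0072). The list medians were -0.50 and -0.42, and the lists tested lower at adjusted p of 6.13e-08 and 9.12e-08, against 0.468 and 0.407 with an estimated correlation. Cdc6, Bub1 and Cxcl10 were looked up here after their values were seen. Cdc6 had a log2 difference of -0.76 ± 0.35 (adjusted p = 0.272) and Bub1 of -0.63 ± 0.30 (adjusted p = 0.286). No interferon-response gene passed over all genes and 6 were lower adjusted over the list alone, with a median of -0.71 and an adjusted p of 6.61e-08 (0.392 with an estimated correlation). Cxcl10 was at -1.20 ± 0.44 (adjusted p = 0.152). The genes that fell furthest included Fndc4, a fibronectin-domain gene, at -1.15 ± 0.25 (adjusted p = 0.00899), the transcription factor gene Nfib at -0.83 ± 0.15 and the protocadherin gene Pcdh18 at -0.81 ± 0.17.

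In all 461 genes were higher and 195 lower in 25,26 than in Null, with 104 and 4 of them at least 2-fold, and the total of 656 became 2167 with the title number as a block, 1164 higher and 1003 lower. Without 25,26 replicate 3 the total was 415, and with the level of Xist, which differed between these groups, as a covariate it was 346. It was 1435 with array weights and 422 with the Null Cre arrays alone.

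**Figure D2:**
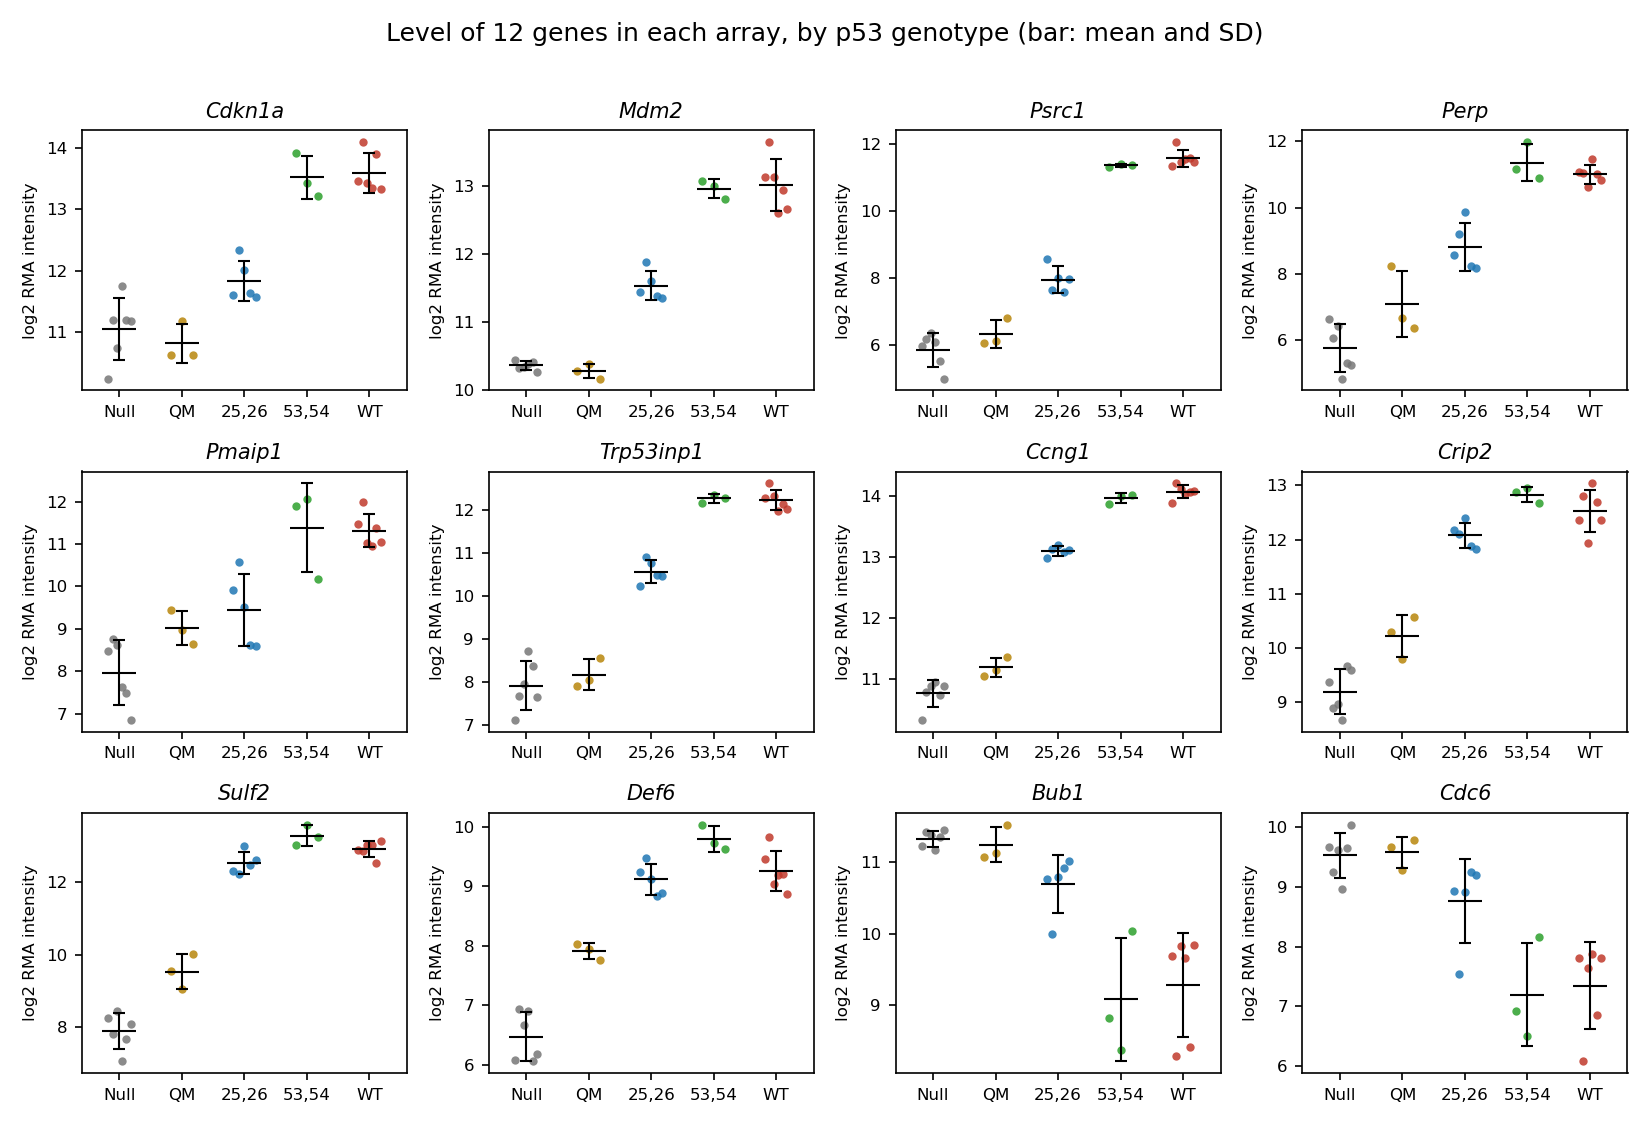
Log2 RMA intensity of 12 genes in each array (points) for Null, QM, 25,26, 53,54 and WT, with the bar at the group mean and its SD. Sulf2 had mean levels of 7.89 in Null, 12.52 in 25,26 and 12.92 in WT, while Psrc1 had 5.84, 7.94 and 11.56.

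The comparison of 25,26 with WT asked what was lost with the first activation domain. Psrc1 fell by 3.62 (SE 0.21, n = 5 and 6), Ephx1 by 2.92 and Eda2r by 2.36. Cdkn1a fell by 1.75 (SE 0.22, adjusted p = 3.93e-05), Mdm2 by 1.49 and Pmaip1 by 1.87. Of the genes recalled from published work as retained by 25,26, a list in part chosen on these samples, several did not pass: Def6 had a log2 difference of -0.15 ± 0.18 (adjusted p = 0.732), Sidt2 of 0.06 ± 0.11 (adjusted p = 0.833), Crip2 of -0.46 ± 0.20 (adjusted p = 0.188) and Polk of -0.30 ± 0.19 (adjusted p = 0.392). Sulf2, looked up here after its values were seen, was at -0.40 ± 0.21 (adjusted p = 0.303). Apaf1 was higher in 25,26 than in WT, at 0.63 ± 0.14.

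Of the 20 arrest targets 12 fell and 2 rose, of the 18 apoptosis targets 11 fell and 1 rose, and of the 16 repair and redox targets 4 fell and 1 rose. Adjusted over the list alone 13, 13 and 7 fell and 2, 1 and 1 rose. These lists had adjusted p of 0.00427, 0.00237 and 0.021 with an estimated correlation. Trp53inp1 fell by 1.66, Btg2 by 1.62, Rprm by 1.81 and Phlda3 by 1.83. Of the 11 genes recalled from published work 3 fell (4 adjusted over the list alone), with an adjusted p of 1.25e-05 (0.0994 with an estimated correlation), and that count is not independent evidence. Of 31 mitosis genes 26 were higher in 25,26 than in WT (31 adjusted over the list alone), with Bub1b at 1.56 ± 0.26 and the centromere gene Cenpa at 1.41 ± 0.22. The list's adjusted p was 8.62e-24, and 0.106 with an estimated correlation. Of 29 replication genes 17 were higher (26 adjusted over the list alone), at an adjusted p of 3.64e-17 (0.0994 with an estimated correlation), with Brca1 at 1.08 ± 0.19. Of 15 contractile genes 5 fell (9 adjusted over the list alone), at an adjusted p of 1.31e-05 (0.0782 with an estimated correlation). The matricellular gene Ccn2 was among them at -2.24 ± 0.33. The largest falls also included Crct1 at -2.94 ± 0.46 and the involucrin gene Ivl at -2.78 ± 0.35. Tmem26, a membrane protein gene, rose by 2.04 ± 0.22, the growth-factor gene Mdk by 1.93 ± 0.39 and the netrin gene Ntn1 by 1.64 ± 0.23.

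In total 663 genes were higher and 513 lower, and the total of 1176 became 1828 with the title number, which paired these arrays, as a block. It was 734 without 25,26 replicate 4, 713 without 25,26 replicate 5, 2288 with array weights, 648 with the compared arrays alone and 505 with LSL-WT Cre alone as WT. Of the 1668 genes higher in WT than in Null, 442 were lower in 25,26 than in WT and 9 higher, and 81 differed from both WT and Null.

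The comparison of 53,54 with Null asked what p53 with a disrupted second activation domain still did. Perp rose by 5.60 ± 0.43 (n = 3 and 6), Psrc1 by 5.51 ± 0.25 and Sulf2 by 5.39 ± 0.25. Cdkn1a rose by 2.47 ± 0.26 (adjusted p = 5.07e-07) and Mdm2 by 2.60 ± 0.16. Fas rose by 2.86 ± 0.26, Icam1 by 2.88 ± 0.40 and Celf5, an RNA-binding protein gene, by 4.96 ± 0.35. The mitotic kinase gene Plk1 fell by 2.15, Bub1 by 2.24 and Cdc6 by 2.33.

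Of 20 arrest targets 13 rose and 1 fell (16 and 1 adjusted over the list alone), including Ccng1 at 3.20 ± 0.11 and Rprm at 2.40 ± 0.24. Of 18 apoptosis targets 12 rose and 1 fell (13 and 2 adjusted over the list alone), including Pmaip1 at 3.42 ± 0.47 and Eda2r at 3.96 ± 0.25. Of 16 repair and redox targets 9 rose and 2 fell (12 and 3 adjusted over the list alone), with Ephx1 at 3.18 ± 0.26. The adjusted p with an estimated correlation were 0.00192, 0.00192 and 0.00209. All 11 genes recalled from published work rose, over all genes and adjusted over the list alone, which is not independent evidence, with Def6 at 3.32 ± 0.21 and Crip2 at 3.64 ± 0.23. All 31 mitosis genes fell by both adjustments, with a median of -1.90 and an adjusted p of 1.22e-23 (0.125 with an estimated correlation). Of 29 replication genes 27 fell (29 adjusted over the list alone), at an adjusted p of 1.49e-20 (0.0743 with an estimated correlation). The replicative helicase gene Mcm3 fell by 1.80 and Pcna by 1.08. Of 20 interferon-response genes 3 fell (3 adjusted over the list alone), at an adjusted p of 0.022 (0.772 with an estimated correlation), and the call of Cxcl10 at -1.97 ± 0.52 (adjusted p = 0.0085) ended without 53,54 replicate 1, at -1.80 and an adjusted p of 0.0509. The calls of Oasl1 and Ifit2 ended without that array too, and each ended for 6 of the 9 arrays left out in turn. Among epithelial markers Dsp rose by 3.40 ± 0.52.

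With limma 1407 genes were higher and 1579 lower, and the total of 2986 became 4847 with the title number, which paired these arrays, as a block. Without 53,54 replicate 2 it was 1923, with array weights 5457 and over all probe sets 4956.

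The comparison of 53,54 with WT asked what was lost with the second activation domain. Most of the genes that passed were higher in 53,54. Plek2, which encodes a pleckstrin-domain protein of the cell cortex, rose by 1.99 ± 0.30 (n = 3 and 6, adjusted p = 0.00214) and Smtnl1, a smoothelin-like muscle gene, by 1.68 ± 0.14 (adjusted p = 7.48e-07). The p53 targets Cdkn1a and Mdm2 were both at -0.07, with adjusted p of 0.984 and 0.976. Of the p53 target lists 1 gene passed, the death-receptor gene Fas, at 1.31 ± 0.26 (adjusted p = 0.0233). The Fas call ended with the title number as a block, at 1.23 (adjusted p = 0.0605), and without each of 53,54 replicates 1, 2 and 3 and WT replicates 3, 5 and 6, at adjusted p of 0.0623, 0.329, 0.0608, 0.0553, 0.0553 and 0.0509. Adjusted over the list alone 2 apoptosis targets were higher and 2 lower, and the median of that list was -0.09, its mean 0.04 and its test pointed down (adjusted p = 0.989). No other fixed list had a member past the threshold over all genes. The 11 genes recalled from published work tested higher at an adjusted p of 1.57e-05 (0.365 with an estimated correlation), with 0 passing and 3 adjusted over the list alone, a count that is not independent evidence. The mitosis and replication lists had medians of -0.24 and -0.31 and adjusted p of 0.0126 and 0.00329 (0.913 each with an estimated correlation).

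In limma 49 genes were higher and 7 lower in 53,54 than in WT (1100 at an unadjusted p under 0.05), and the total of 56 became 158 with the title number as a block. It was 14 without 53,54 replicate 1, 11 without 53,54 replicate 2, 143 without WT replicate 2, 37 without WT replicate 3 and 30 without WT replicate 5. With array weights it was 734 (459 higher and 275 lower), with the compared arrays alone 3, with LSL-WT Cre alone as WT 7, with a mean above the median 37 and without the differing labels 33. Of the 1668 genes higher in WT than in Null, 3 were lower in 53,54 than in WT and 28 higher.

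The comparison of QM with Null asked what p53 with both activation domains disrupted still did. Sulf2 was higher in QM by 1.64 ± 0.25 and Def6 by 1.44 ± 0.21 (n = 3 and 6, adjusted p = 0.00914 each). These were the only genes that passed in limma, with 377 at an unadjusted p under 0.05. Both are among the genes that 25,26 raised. The call of Sulf2 ended without QM replicate 1 (1.64, adjusted p = 0.177) or replicate 3 (1.40, adjusted p = 0.216), and the call of Def6 ended without QM replicate 1 (1.38), 2 (1.42) or 3 (1.51), at adjusted p of 0.177, 0.131 and 0.101. The count of 2 became 0, 1 and 0 without QM replicates 1, 2 and 3 and 0 with the compared arrays alone. It became 23 (13 higher and 10 lower) with the Null Cre arrays alone, 7 with array weights and 4 over all probe sets.

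Other p53 targets did not pass in QM: Perp was at 1.34 ± 0.43 (adjusted p = 1), Crip2 at 1.03 ± 0.23 (adjusted p = 0.437), Zmat3 at 0.67 ± 0.15 (adjusted p = 0.48), Ccng1 at 0.42 ± 0.11 (adjusted p = 0.815), Cdkn1a at -0.24 ± 0.26 and Mdm2 at -0.08 ± 0.16 (adjusted p = 1 each). Some leaned lower in QM and did not pass either, as the apoptosis-associated gene Ei24 at -0.82 ± 0.17 (adjusted p = 0.239) and Fas at -0.70 ± 0.26. Of the 11 genes recalled from published work 1 rose, Def6 (4 adjusted over the list alone), which is not independent evidence, at an adjusted p of 2.97e-09 (0.0655 with an estimated correlation). Of the 16 repair and redox targets 0 passed and 2 were higher adjusted over the list alone, at an adjusted p of 0.00477 (0.196 with an estimated correlation). Matrix genes had a median of -0.29 and an adjusted p of 2.03e-06 (0.251 with an estimated correlation), with 0 of 21 passing. Contractile genes had a median of -0.19 and an adjusted p of 7.46e-04 (0.196 with an estimated correlation), with 0 of 15 passing. The mitosis genes had a median of -0.01 (adjusted p = 0.704).

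The comparison of QM with WT asked what was lost with both domains. Psrc1 fell by 5.25 (SE 0.25, n = 3 and 6), Trp53inp1 by 4.05, Perp by 3.91 and Ephx1 by 3.83. Cdkn1a fell by 2.77 (adjusted p = 2.41e-07), Mdm2 by 2.75 and Ccng1 by 2.88. Def6 fell by 1.36 and Crip2 by 2.31. Cxcl10 was higher in QM by 2.98 ± 0.52, Oasl1 by 2.33 ± 0.46 and Tmem26 by 2.40 ± 0.26.

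Of 20 arrest targets 13 fell and 1 rose, of 18 apoptosis targets 13 fell and 1 rose, and of 16 repair and redox targets 7 fell and 1 rose, the last being Pcna at 0.72 ± 0.17. Adjusted over the list alone 13, 14 and 7 fell and 1 rose in each, and with an estimated correlation the lists had adjusted p of 8.12e-04, 8.12e-04 and 0.00297. Of the 11 genes recalled from published work 10 fell by both adjustments, a count that is not independent evidence. All 31 mitosis genes were higher by both adjustments, with a median of 1.58 and an adjusted p of 3.49e-25 (0.0919 with an estimated correlation), including Nek2, a centrosomal kinase gene, at 1.88 ± 0.25. Of 29 replication genes 24 were higher (25 adjusted over the list alone), at an adjusted p of 8.84e-21 (0.0701 with an estimated correlation), including Uhrf1, a DNA methylation factor gene, at 1.55 ± 0.19. Of 20 interferon-response genes 3 were higher (3 adjusted over the list alone), at an adjusted p of 0.00398 (0.726 with an estimated correlation). Of 15 cholesterol-synthesis genes 4 were higher (9 adjusted over the list alone), at an adjusted p of 1.59e-04 (0.387 with an estimated correlation). The calls of Lss, Sqle, Dhcr7 and Insig1 each ended without QM replicate 1, and again without QM replicate 2. Of 15 contractile genes 3 fell (5 adjusted over the list alone), at an adjusted p of 1.40e-04 (0.0919 with an estimated correlation), with Ccn2 at -1.95 ± 0.39. The calls of Myl9 and Lmod1 ended without QM replicate 1. Among epithelial markers Dsp fell by 2.51.

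With limma 1246 genes were higher and 879 lower in QM than in WT. The total of 2125 was 1411 without QM replicate 1, 1399 without QM replicate 3, 1284 with the compared arrays alone and 4025 with the title number as a block.

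The comparison of 25,26 with QM asked what the second activation domain added where the first was disrupted. Sulf2 was higher in 25,26 by 2.99 ± 0.25 (n = 5 and 3, adjusted p = 6.99e-07), Trp53inp1 by 2.39 ± 0.25, Ccng1 by 1.91 ± 0.11 and Crip2 by 1.86 ± 0.24. Psrc1 rose by 1.63 ± 0.26, Zmat3 by 1.26 ± 0.16, Ei24 by 1.46 ± 0.18 and Phlda3 by 1.38 ± 0.20. For Ei24 the QM arrays lay below Null, at -0.82 ± 0.17, which is part of that difference. The retinoblastoma gene Rb1 was higher by 1.25 ± 0.20 (adjusted p = 0.00195). Cdkn1a at 1.01 ± 0.27 (adjusted p = 0.0915) and Perp at 1.72 ± 0.44 (adjusted p = 0.0839) did not pass, and both passed with the title number as a block, at 1.11 (adjusted p = 0.00138) and 2.08 (adjusted p = 0.0105). Recql4, a DNA helicase gene, fell by 0.67.

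Of 20 arrest targets 5 rose (10 rose and 1 fell adjusted over the list alone), of 18 apoptosis targets 6 rose (8 and 1) and of 16 repair and redox targets 4 rose (5 adjusted over the list alone), at adjusted p of 0.00299, 0.00473 and 0.00542 with an estimated correlation. Among the apoptosis targets the calls of Apaf1 and Fas ended without QM replicate 1 or 2, and that of Eda2r without QM replicate 2. Of the 11 genes recalled from published work 8 rose (10 adjusted over the list alone), with Abhd4 at 1.12 ± 0.12, and this is not independent evidence. No gene of the mitosis list passed, where 1420 genes in all had an unadjusted p under 0.05 in limma. The list had a median of -0.48 and an adjusted p of 9.08e-08 (0.541 with an estimated correlation). No gene of the replication list passed either (1 lower adjusted over the list alone), at an adjusted p of 7.61e-09 (0.361 with an estimated correlation). Off the list, the DNA polymerase subunit gene Pold2 passed as lower. That call ended for 7 of the 8 arrays left out in turn. With the title number as a block 1 mitosis gene and 7 replication genes were lower.

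In all 91 genes were higher and 12 lower, and the total of 103 became 603 with the title number as a block, 347 higher and 256 lower. The total was 64 without 25,26 replicate 3 and 52, 50 and 59 without QM replicates 1, 2 and 3, and 506 with array weights.

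The sizes of the p53 responses were set side by side with scores whose choosing and scoring differences shared no array. The moderated statistic that ranked the genes took its variance from all arrays, the scored ones included. The choice was therefore not fully independent of the spread of the scores. The 100 genes raised most and the 100 lowered most in the LSL-WT part were averaged in each array of the other groups and compared with the 3 Null Cre arrays. The score of raised genes was higher by 2.03 (SD 0.127, n = 3) in WT, 1.15 (SD 0.122, n = 5) in 25,26, 2.41 (SD 0.132, n = 3) in 53,54 and 0.18 (SD 0.029, n = 3) in QM. As shares of the WT value these were 56.5% in 25,26, 118.8% in 53,54 and 8.9% in QM. The score of lowered genes differed by -0.93 in WT, -0.37 in 25,26, -1.15 in 53,54 and 0.12 in QM, or 40.4% of WT in 25,26, 124.5% in 53,54 and -13.0% in QM. The sign of the QM value turned when the parts were swapped between choosing and scoring, at -0.012 (exact p = 0.8). With that swap the shares of 53,54 were 104.5% for raised and 104.1% for lowered genes. By the level of Xist the 3 WT and the 3 Null Cre arrays of these scores were of opposite sex. All 5 arrays of 25,26 and all 3 of QM had higher scores of raised genes than each Null Cre array.

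Exact two-sided permutation tests gave p = 0.0179 for 25,26 against Null Cre in each direction, the smallest p that 5 against 3 arrays allow, and 0.0716 after adjustment over 4 tests. Without 25,26 replicate 4 the lowered score of 25,26 was -0.39, at an exact p of 0.0571. The other groups had 3 arrays each, where the smallest exact p is 0.1. Directly compared, the raised-gene score of 25,26 was -0.88 against WT, 0.97 against QM and -1.26 against 53,54 (exact p = 0.0179 each, 0.0298 adjusted over 5 tests). The scores of 53,54 differed from WT by 0.38 for raised genes (exact p = 0.1) and -0.23 for lowered genes (exact p = 0.2). Within title numbers 2, 3 and 4 the raised-gene score of 25,26 lay above Null Cre by 1.22, 1.34 and 1.02, and within numbers 2 and 3 that of QM lay above it by 0.14 and 0.23.

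**Figure D3:**
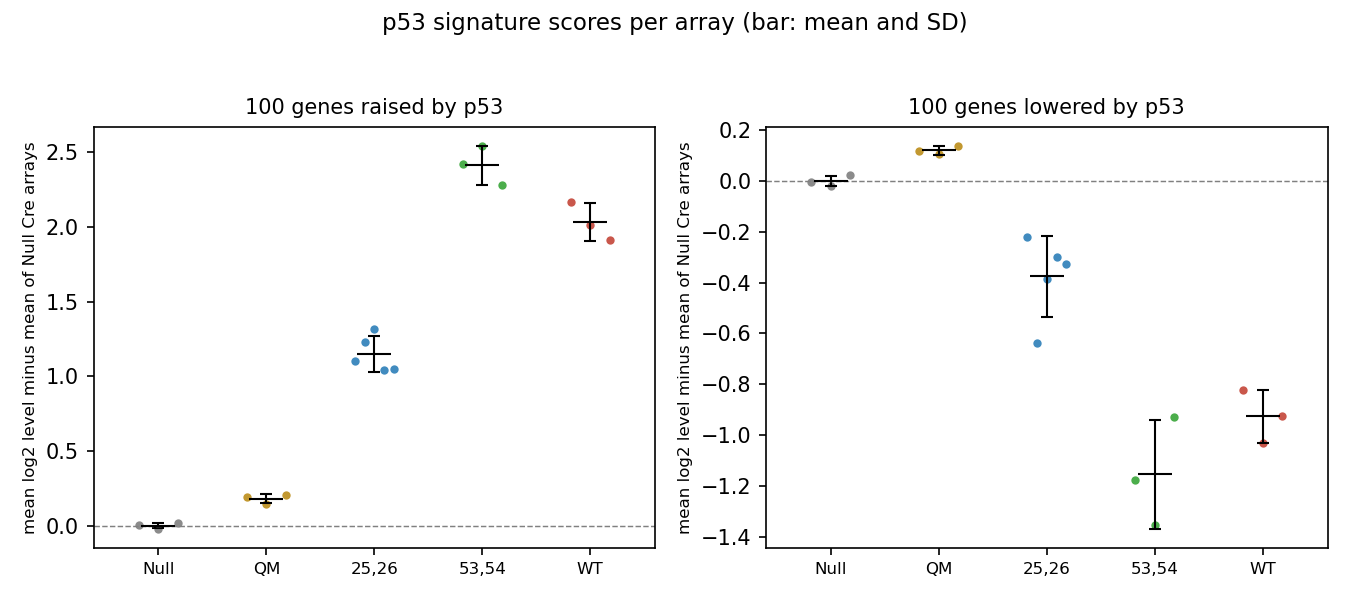
Mean log2 level of the 100 genes raised and the 100 genes lowered by p53 in the LSL-WT arrays, relative to the mean of the Null Cre arrays, for each array (points) of Null, QM, 25,26, 53,54 and WT, with the bar at the mean and its SD. For the raised genes the 25,26 arrays average 1.15, between QM at 0.18 and WT at 2.03.

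The overlap of the mutant effects with the WT effect was counted over the 15266 genes. Of the 461 genes higher in 25,26 than in Null, 379 were also higher in WT, where 50.4 were expected from independent sets, and of the 195 lower genes 162 were also lower, where 22.9 were expected. For 53,54 these were 1067 of 1407 (153.7 expected) and 1268 of 1579 (185.9 expected), and for QM both higher genes, Sulf2 and Def6, were also higher in WT. These overlaps share the Null arrays, which raises them by itself. Across genes, which are not independent replicates, the log2 differences of 25,26 and WT had a correlation of 0.713 with shared Null arrays, 0.476 in 100 simulations of unchanged groups and 0.511 with the Null arrays split between both sides. For 53,54 the values were 0.894, 0.407 and 0.796, and for QM they were 0.292, 0.408 and 0.003. The covariance beyond the simulated one was 0.0801 for 25,26, 0.1977 for 53,54 and 0.0102 for QM. The simulations drew each array independently, without the component that arrays of 1 title number share. In them WT was unchanged too, while the observed correlations include the WT effect. The simulated correlations are therefore no baseline for the observed ones. With the Null arrays split, in each of the possible ways, the covariance was 0.0776 and 0.069 for 25,26, 0.1975 and 0.1843 for 53,54, and 4e-04 and 0.0065 for QM.

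**Figure D4:**
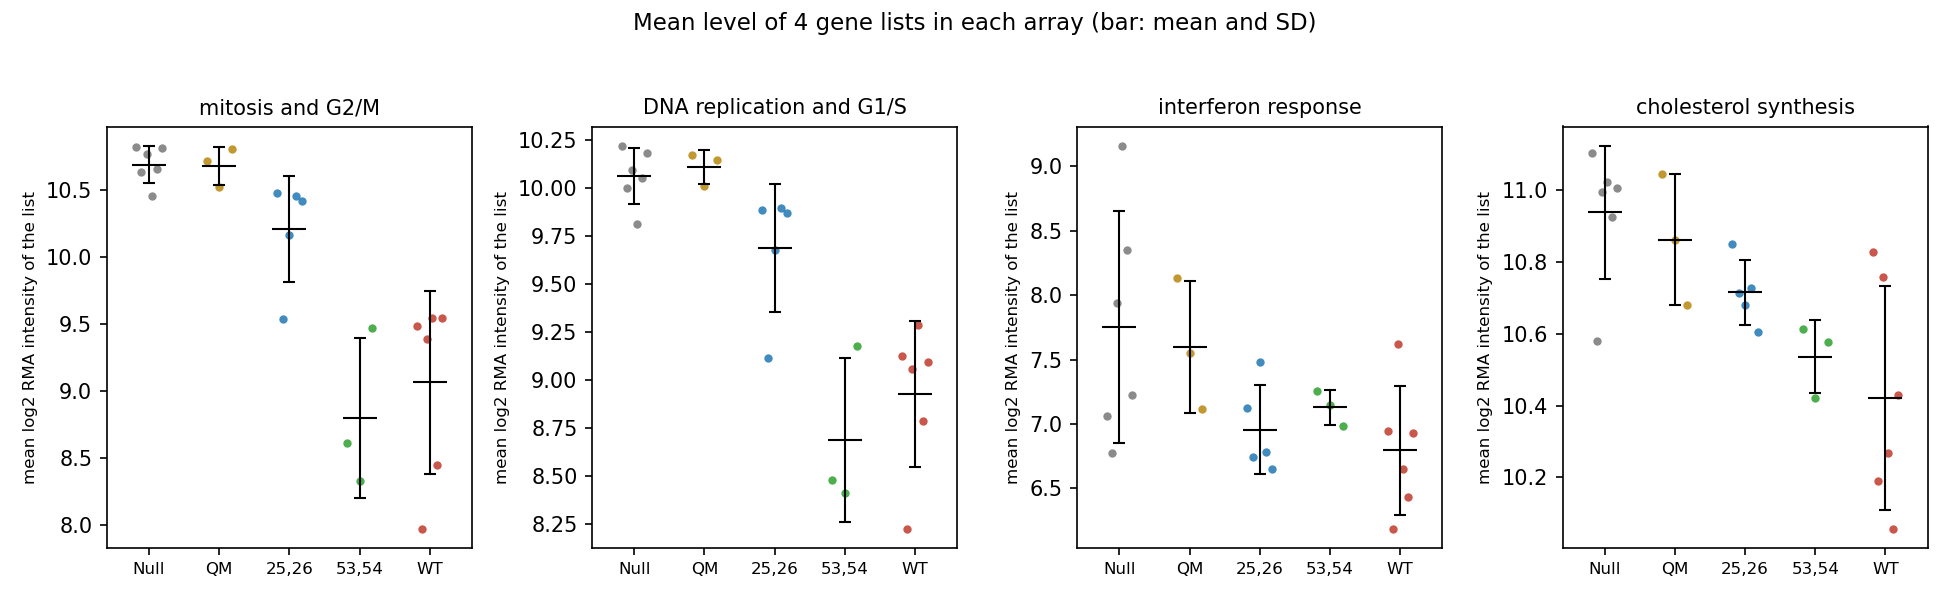
Mean log2 level per array (points) of the mitosis, replication, interferon-response and cholesterol-synthesis lists in Null, QM, 25,26, 53,54 and WT, with the bar at the mean and its SD. The median gene of the mitosis list differed from Null by -1.64 in WT, -1.90 in 53,54, -0.50 in 25,26 and -0.01 in QM.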

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

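The tests of Sulf2 and Def6 in QM, of the arrays of title number 2 and of the interferon-response genes were chosen only after those results were seen, and the counts over other splits of the samples were planned. An array whose gap to the nearest other array of its group was large against the whole range was picked out, which chance does in about 1 in 20 groups. Of 74 sets of list means and scores 7 had such an array, and of 975 sets of named-gene levels 73 did (7.49%).

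Among the lists, DNA replication in 25,26 replicate 2 had a gap of 0.717 of the range, with a mean log2 level of 9.11 against 9.83 in the other arrays of its group. The unfolded-protein list in 25,26 replicate 3 had a gap of 0.716, at 11.3 against 11.1. The p53 arrest targets in WT replicate 2 had a gap of 0.687, at 10.5 against 10.1, and the muscle markers in that array 0.71, at 6.16 against 6.50. Cartilage markers in WT replicate 6 had a gap of 0.632, at 7.39 against 6.76. The repair and redox targets in Null replicate 4 had a gap of 0.63, at 8.93 against 8.74, and cholesterol synthesis in Null replicate 2 had 0.662, at 10.58 against 11.01. Lrp11 was picked out because its response differed between the LSL-WT arrays and the WT Cre and Null Cre arrays, by -1.72 ± 0.26. The control probe sets for Cre, outside the gene tables, had a log2 level relative to the bioD control of 2.63 (SD 0.144, n = 20) in Cre arrays and 2.002 (SD 0.102, n = 3) in Empty arrays, a difference of 0.632, and all 20 Cre arrays lay above the highest Empty array.

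Sulf2 and Def6 were higher in QM, whose p53 has both activation domains disrupted. Wild-type RNA in the QM arrays is argued against, since it would bring all strongly raised genes alike. Over 8 other genes at least 16-fold higher in WT the rise of intensity over Null in QM was a median of 0.767% of the rise in WT (SD 1.57, highest 5.05 for Perp). The rise was 6.91% for Sulf2 (3.7 to 10.5 over the QM arrays) and 27.8% for Def6 (23.1 to 31.4). The lowest Sulf2 array lay below the mean of Perp, so the argument is clearer for Def6. Def6 itself rose less than 16-fold in WT. Differences between title numbers are argued against as well, because with the title number as a block both stayed past the threshold (higher adjusted p = 9.34e-04). Activity left in QM at genes that 25,26 holds near the WT level cannot be told apart from chance. Of the genes at least 2-fold higher in WT, 82 such genes averaged 0.33 higher in QM than in Null and 221 other genes 0.11. The difference of 0.219 was reached by 3 of 84 splits of the arrays, the real one included (highest other 0.289). The genes were chosen anew in each split. With no array shared between the choosing and scoring differences, the value was 0.0638 and 0.147. Of 20 splits, 4 and 1 reached these values. The variance used in that choice still came from all arrays. The count of 2 genes itself was reached by 5 of 84 splits, with 69 genes in the highest other and 1 in the highest other of the 18 that parted at least as many pairs of title numbers, so chance is not excluded for it, and each call ended when QM arrays were left out, as for Sulf2 without QM replicate 1 or 3 (1.64 and 1.40) and for Def6 without QM replicate 1, 2 or 3 (1.38, 1.42 and 1.51).

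The 7 arrays with the number 2 in their titles stood apart in every subgroup, with values of 0.225 to 0.361 on the first component within subgroups against at most 0.024 in the other arrays. RNA quality or labelling cannot be decided, since the control probe sets disagreed. The difference between the 3' and 5' actin control probe sets was lowest in the array of number 2 in 7 of 7 subgroups (0.059 to 0.125 against 0.203 to 0.406, chance 2.74e-04). The same difference for Gapdh was highest in that array in most subgroups, as in WT Cre (0.039 against -0.072 and -0.034). The exception was 25,26, at -0.001 against 0.005 in replicate 3. Fewer cycling cells in the arrays of number 2 are argued against as the whole of the pattern. The Null arrays of number 2 had 0.918 of the component of the WT arrays of that number but 0.233 of their lower cell-cycle level (-0.15 against -0.65 over 60 genes). A shared day of preparation stays open, since the labels give no dates, and no other biological explanation was tested.

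The interferon-response list was lower in WT than in Null by 0.957 (SE 0.343), and by 1.57 (SE 0.579) between WT Cre and Null Cre arrays, of which the Null arrays were scattered from 7.23 to 9.16 and were of the opposite sex. A difference between embryos of those lines alone cannot be decided. LSL-WT arrays with Cre lay below their same-number partners with Empty virus in 3 of 3 pairs (mean -0.342, SE 0.137). But 3 pairs are few, and their arrays differed in virus as well. Sex of the embryos as the whole is argued against, because with the level of Xist as a covariate the list stayed at -0.826 (SE 0.366) and Cxcl10 at -2.60 (adjusted p = 1.39e-04), with 3 of its members past the threshold. Activity of p53 and differences between embryos cannot be told apart: the 53,54 arrays had the list at -0.624 (SE 0.42) against Null, too near 0 for its SE to decide. The list averaged 6.795 (SD 0.499) in WT, 6.96 (SD 0.343) in 25,26, 7.13 (SD 0.137) in 53,54, 7.598 (SD 0.512) in QM and 7.75 (SD 0.904) in Null. The difference between 25,26 and 53,54 lay within these spreads. The means therefore cannot tell whether the list followed the size of the p53 response. The difference between the LSL-WT and the other arrays (1.23) and a response to virus stay open and were not tested further.

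Other splits of the samples into groups of the same sizes were counted for each comparison, the real split included. For WT with Null 1 of 100 splits reached the real 3465 genes (highest other 1521), for 25,26 with Null 1 of 100 reached 656 (243) and for 53,54 with Null 1 of 84 reached 2986 (99). For QM with WT 1 of 84 reached 2125 (965), for 25,26 with QM 1 of 56 reached 103 (0) and for 25,26 with WT 1 of 100 reached 1176 (650). These shares are under 0.05. They take the arrays as exchangeable, which arrays of 1 title number may not be, so chance is less likely but not excluded. Among the splits that parted at least as many pairs of title numbers as the real one the highest others were 737 for WT with Null, 243 for 25,26 with Null, 55 for 53,54 with Null, 376 for 25,26 with WT, 438 for 53,54 with WT, 421 for QM with WT and 1 for QM with Null. For 53,54 with WT 5 of 84 splits reached 56, so chance is not excluded, and the highest other, 1171, set all arrays of title number 2 against the rest, which points to a structure of the samples, and with the title number as a block the real split gave 158. For the LSL-WT part and for WT Cre with Null Cre the 10 splits are too few for a share under 0.05. The real splits gave 1785 and 2433 there and the highest others 1 and 10. For the interaction 23 of 100 splits reached 1 gene (highest other 305), so chance is not excluded.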

How the results depend on the processing

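The Xist covariate, the arrays without title number 2 and those without differing labels were chosen after seeing the data. The other alternatives were planned. No named-gene call changed direction in 19768 values, from no filter, quantile normalization, the strain background, the title-number block and single arrays left out. No list call did in 864, from the estimated correlation, no filter, the strain background, the block and the Null Cre arrays alone. Both totals include genes and lists without a call in the main fit, which could not count as a change of direction. Named genes and lists were not checked under the other settings. With no filter and with trended, robust variances the 11 counts stayed within 1.5 times. Quantile normalization moved the median of all genes by at most 0.00488 and median centring by 0.037. Of 192 list tests, 40 lost their call with an estimated correlation. With a mean above the median, 11470 genes were tested and 10 of 11 counts stayed within 1.5 times, while 53,54 against WT had 37. Signal over background may limit weakly expressed genes, which was not tested. For the changes below the cause was not tested, except that fewer arrays or more features were used where the setting says so.

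With the mean of probe sets the interaction had 2 genes. With all probe sets the counts were 5746 for WT against Null, 4956 for 53,54 against Null, 4 for QM against Null, 2813 for the LSL-WT part, 4236 for WT Cre against Null Cre and 7 for the interaction. Quantile normalization gave the interaction 12 genes, median centring 13 and the strain background 9. Median centring gave QM scores of 0.237 for raised and 0.161 for lowered genes.

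The replicate block (title number) gave 2167 for 25,26 and 4847 for 53,54 against Null, 1828, 158 and 4025 for 25,26, 53,54 and QM against WT, 603 for 25,26 against QM, 4078 for the LSL-WT part, 4297 for WT Cre against Null Cre and 245 for the interaction. Within the 6 LSL-WT arrays alone, paired, the count was 4667. Array weights gave 1435, 5457 and 7 for 25,26, 53,54 and QM against Null, 2288 and 734 for 25,26 and 53,54 against WT, 506 for 25,26 against QM and 24 for the interaction. The compared arrays alone gave 0 for QM against Null in limma, 648, 3 and 1284 for 25,26, 53,54 and QM against WT, 807 for the LSL-WT part, 1186 for WT Cre against Null Cre and 0 for the interaction. With Null Cre arrays alone 25,26 had 422 and QM 23. With LSL-WT Cre alone as WT 25,26 had 505 and 53,54 had 7. With the Xist covariate 25,26 against Null had 346, WT Cre against Null Cre 1306 and the interaction 0. Without title number 2 the LSL-WT part had 1157 and the interaction 4. Without the differing labels 53,54 against WT had 33 and the interaction 15.

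Scores of 50 genes were 2.627 in WT, 2.957 in 53,54 and 0.29 in QM. Scores of 200 were 1.561, 1.894 and 0.15, with 0.09 for lowered genes in QM. With the genes chosen in WT Cre against Null Cre and scored against the LSL-WT Empty arrays, WT had 1.871, 53,54 had 1.955 and the lowered genes of QM had -0.012. With the Null arrays split the other way the correlations with WT were 0.452, 0.7 and 0.076 for 25,26, 53,54 and QM.

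With 1 array left out, counts ranged from 3036 to 3472 for WT against Null and 1648 to 2571 for WT Cre against Null Cre. They ranged from 415 (without 25,26 replicate 3) to 593 for 25,26 against Null, 1923 (without 53,54 replicate 2) to 2985 for 53,54 against Null and 0 to 2 for QM against Null (0, 1 and 0 without QM replicates 1, 2 and 3). Against WT 25,26 had 713 to 1329 (713 and 734 without 25,26 replicates 5 and 4) and QM had 1399 to 2141 (1399 and 1411 without QM replicates 3 and 1). The count of 53,54 against WT ran from 11 to 143, with 11 and 14 without 53,54 replicates 2 and 1, and 143, 37 and 30 without WT replicates 2, 3 and 5. That of 25,26 against QM ran from 50 to 110, with 52, 50 and 59 without QM replicates 1, 2 and 3 and 64 without 25,26 replicate 3. The LSL-WT part ran from 994 (without WT replicate 2) to 1661. The interaction ran from 0 (without WT replicate 1, 2 or 3 or Null replicate 1, 2, 3, 5 or 6) to 47 (without WT replicate 6), with 3 without WT replicate 5. The lowered score of 25,26 ranged from -0.413 to -0.308 and missed the threshold without 25,26 replicate 4 (-0.393, exact p = 0.0571).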

Other observations

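Genes of the senescence, metabolism and stress lists, some of which are also on the p53 lists, differed between WT and Null (log2 difference ± SE, n = 6 and 6). Of 15 senescence regulators 3 rose and 5 fell in WT (5 and 6 adjusted over the list alone; adjusted p of the list = 0.915). The retinoblastoma gene Rb1 rose by 2.09 ± 0.16 and Pml, the nuclear-body gene, by 1.30 ± 0.16, while the histone methyltransferase gene Ezh2 fell by 0.83. Rb1 was also higher than in Null by 1.09 ± 0.17 in 25,26 and by 2.68 ± 0.20 in 53,54. Of 16 genes of unfolded-protein and amino-acid stress 3 rose and 6 fell in WT (adjusted p = 0.339). Sesn2, an inhibitor of growth signalling that is also on a p53 list, rose by 1.32 ± 0.16 and Ddit4, another such inhibitor, by 1.13 ± 0.20, while the serine-glycine gene Shmt2 fell by 0.93.

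Of 14 glycolysis genes 1 rose and 4 fell in WT (1 and 6 adjusted over the list alone), at an adjusted p of 0.0357 (0.475 with an estimated correlation), with Tpi1 at -0.47 ± 0.07 and Pdk1, a brake on pyruvate oxidation, at -1.15 ± 0.22. Of 13 genes of the NRF2 antioxidant response 3 rose and 1 fell (adjusted p = 0.889), with the haem oxygenase gene Hmox1 at 1.72 ± 0.24 and the cystine transporter gene Slc7a11 at -0.996 ± 0.21. Of 22 genes of MAPK output downstream of Ras 4 rose and 1 fell (adjusted p = 0.397), with the ephrin receptor gene Epha2 at 1.06 ± 0.24 and Myc at -0.43 ± 0.10. The means of the actin difference between 3' and 5' control probe sets were 0.291 in 25,26, 0.214 in 53,54, 0.212 in QM, 0.204 in WT and 0.206 in Null.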
